A study of Gallus gallus with 2 samples.

How the data were processed

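A suspension of cells from whole chicken embryos at Hamburger-Hamilton stage HH5, a gastrula stage, was profiled with the 10x Multiome assay, which reads RNA and accessible chromatin (ATAC) from the same cell. Per the labels, embryos were dissected in Ringer's solution, dissociated with enzymes and processed as 1 preparation, which gave 1 RNA library and 1 ATAC library. The labels name the antero-posterior axis for both libraries. There were no replicate preparations and no contrasting treatment or stage.

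The deposited data used here were 1 table with a row per cell barcode. Per the file headers, each row holds a pair of coordinates of a weighted nearest neighbour UMAP, a class name and an ATAC rank. Such an embedding places cells on a plane by the similarity of their RNA and ATAC profiles combined. Both coordinates and the rank were treated as scores deposited by the authors, with no unit. The class names were taken as the authors' own annotation. The ranks were checked to be the whole numbers from 1 to 6681, each used once, with no value for the other 1069 cells. The quantity that was ranked, and which end of the rank is anterior, are not given in the sources used here, so ranks are described only as low or high. Per the submitters' processing notes, Cell Ranger ARC 2.0.0, Seurat 4.3.0, Signac 1.8.0 and the genome build galGal6 were used. Their settings, the filters on cells, the treatment of doublets and the way the classes were named are not given in the sources used here. Gene counts, fragment counts and quality measures per cell were not analysed here, so the depth behind each rank is unknown. No gene is named as a result, and no doublet caller was run.

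Cells were counted per class, and each share is given with its exact (Clopper-Pearson) 95% binomial interval. These intervals, and the limits given for counts of 0 (3 counts of the total), cover counting error only. Ranks were summarised per class by the median and quartiles over cells. Pairs of classes were compared by the percent of all cell pairs in which the cell of one class ranked above the cell of the other, where 50% means no difference in level. The rank was also divided into 10 bins of 668 or 669 cells, numbered from the lowest ranks, to count the tissues in each. Classes were pooled by name into ectoderm (both neural and both nonneural pairs of classes) and mesoderm (mesoderm-1 to mesoderm-6), with the others kept apart. The share of the variance of the rank that lay between classes was computed as the between-class sum of squares over the total. For each cell the 15 nearest other cells in the embedding were found by Euclidean distance (for correlations within a class, among the cells of that class only), and border cells of a class were those with at least 1 of these 15 in the neighbouring class named. Distances in such an embedding are not measured distances in the embryo. The embedding and, by its name, the rank both draw on the ATAC data of the same cells, so relations between them are not between independent measurements. Correlations are across cells of 1 preparation. Cells are not replicates, so no test between classes was made and no p-value is given.

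The rule for what the text names was fixed before the data were examined. It named all annotated classes, and genes only if the table held gene values. The planned summaries of RNA depth, ATAC depth, quality measures and clusters against classes needed columns other than those of the table used here, and were not run. Marker lists written beforehand to name cell types were not used, because the authors' annotation was present. Alternatives tried were means in place of medians, relations within classes, Pearson in place of Spearman correlation, other numbers of nearest cells (5 and 50), the variance share without endoderm or on normal scores of the ranks, and leaving out cells with fewer than 8 of their 15 nearest cells in their own class. The comparison of border cells, the bins of the rank, the pairwise percentages, the share of rank variance between classes, the share of nearest cells of the same class, every use of nearest cells (15, 5 or 50), the pooling into tissues and the divisions of a class by an embedding coordinate were added after the table had been seen. The functions for variance shares, pairwise percentages and nearest cells were tested on simulated data with known answers. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and scikit-learn 1.9.0 were used.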

Results

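The table described 7750 cells of 1 preparation of HH5 chicken embryos, each with an RNA and an ATAC profile. The authors assigned every cell to 1 of 16 classes and gave 6681 cells, 86.2% of the total, an ATAC rank. The series concerns positional information in chromatin accessibility, and the labels name the antero-posterior axis. The comparisons made here were therefore which tissues were captured, how they were arranged along the rank, and how the rank varied inside each tissue. Because there was 1 library of each kind, every value below is the authors' value or a summary of it over cells, without a replicate error, and differences between classes were not tested.

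Cells of all germ layers were captured. Mesoderm was the most frequent, with 2936 cells in 6 classes, or 37.9% of all cells (95% interval 36.8 to 39.0%). Ectoderm followed with 2481 cells, or 32.0% (31.0 to 33.1%). The primitive streak, the midline structure through which cells ingress to form mesoderm and endoderm, made up 710 cells, or 9.16% (8.53 to 9.83%). Embryonic endoderm made up 440 cells, or 5.68% (5.17 to 6.22%). The notochord, the axial mesoderm that underlies the neural plate, was the smallest class, with 114 cells, or 1.47% (1.21 to 1.76%). The extraembryonic side was represented by 498 cells of extraembryonic endoderm, 420 of blood islands, where the first blood and vessel cells form, and 151 of the area opaca, the outer ring of the blastoderm. These 3 classes made up 13.8% of cells (13.0 to 14.6%).

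Within ectoderm, neural classes outnumbered nonneural ones. Neural ectoderm-1 held 791 cells, or 10.2% of all cells (9.54 to 10.9%), and neural ectoderm-2 held 668, or 8.62%. Nonneural ectoderm-2 and nonneural ectoderm-1 held 609 and 413 cells, respectively. The mesoderm classes ranged from 136 cells in mesoderm-3 to 799 in mesoderm-2, the most numerous of all 16 classes. Mesoderm-1 and mesoderm-4 held 783 and 666 cells, and mesoderm-5 and mesoderm-6 held 284 and 268. The intervals cover counting error only. Losses during dissociation and filtering of cells can also set these shares.

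The ATAC rank was given to every cell of 13 classes and to none of the 3 extraembryonic classes. Endoderm and neural ectoderm-1 held the low end. The median rank of endoderm cells was 564.5 (quartiles 155.5 and 1783.75) and that of neural ectoderm-1 cells was 739 (quartiles 424.5 and 1184.5). The other ectoderm classes lay close together, with medians of 2075.5 in neural ectoderm-2, 2102 in nonneural ectoderm-2 and 2275 in nonneural ectoderm-1. Mesoderm-4 held the high end, with a median of 5798.5 (quartiles 5064 and 6279.5). The primitive streak and mesoderm-6 had nearly equal medians of 4654.5 and 4653.5, followed by mesoderm-2 at 4854 and mesoderm-1 at 4944.

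**Figure D1:**
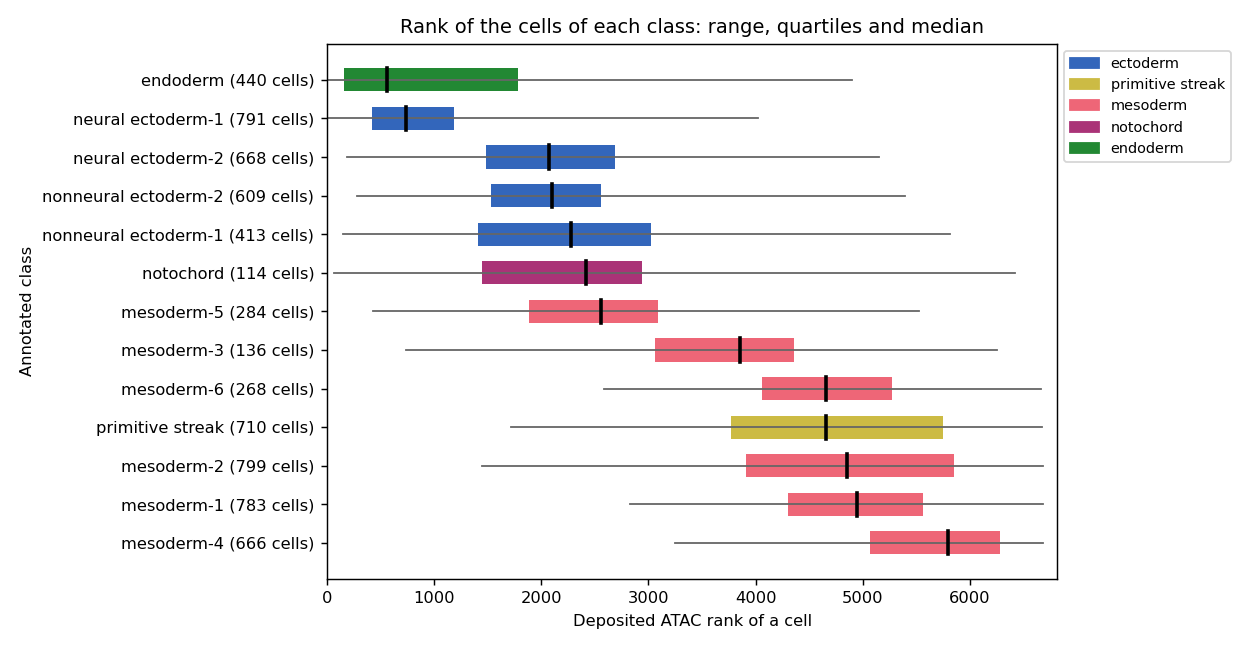
Deposited ATAC rank of the ranked cells (horizontal axis, no unit) for each of 13 annotated classes (vertical axis); the thin line is the range over cells, the coloured bar runs between the quartiles and the black mark is the median. Medians run from 564.5 in endoderm to 5798.5 in mesoderm-4, and mesoderm-5 lies beside the ectoderm classes.

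As pooled tissues, ectoderm and mesoderm were largely separated on the rank. Mesoderm-5 was the main exception, and its cells ranked above ectoderm cells in 57.2% (nonneural ectoderm-1) to 92.7% (neural ectoderm-1) of pairs. A mesoderm cell ranked above an ectoderm cell in 95.9% of pairs, and a primitive streak cell ranked above an ectoderm cell in 98.4%. Mesoderm as a whole ranked above the streak in 52.1% of pairs, but its classes lay on both sides of it. Mesoderm-4 cells ranked above streak cells in 72.9% of pairs, whereas streak cells ranked above mesoderm-3 cells in 72.5% and above mesoderm-5 cells in 95.2%. Of the ectoderm cells, 95.2% lay below the middle rank of 3341, against 12.9% of mesoderm cells and 9.15% of streak cells. The 5 tissues accounted for 65.3% of the variance of the rank and the 13 classes for 77.2%, which left 22.8% within classes. The class column holds cluster names, so the classes may rest in part on the ATAC data that the rank, by its name, draws on. The separation of classes and tissues along the rank may then be partly built in.

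The notochord and mesoderm-5 had lower median ranks than the streak and the other mesoderm classes. The median notochord rank was 2417.5 (quartiles 1444.75 and 2939.25), and a streak cell ranked above a notochord cell in 94.9% of pairs. Of the notochord cells, 89.5% lay below the middle rank and 5.26% were in the highest 4 of 10 nearly equal bins of the rank, with single cells as low as 68 and as high as 6418. Mesoderm-5 had a median of 2559.5 (quartiles 1887.75 and 3087.5), and 85.2% of its cells lay below the middle rank. Its upper quartile reached into the quartile range of mesoderm-3 (3059 to 4359.25), and a mesoderm-3 cell ranked above a mesoderm-5 cell in 79.8% of pairs. Mesoderm-5 overlapped with the notochord (56.7% of pairs with the mesoderm-5 cell higher) and with nonneural ectoderm-1 (57.2%). Mesoderm-4 cells ranked above mesoderm-5 cells in 99.3% of pairs. They ranked above cells of the ectoderm classes in 99.5% (nonneural ectoderm-1) to 99.99% (neural ectoderm-1) of pairs. Classes of mesoderm differed in rank so far that they accounted for 44.9% of the variance among mesoderm cells, and the ectoderm classes for 35.4% of that among ectoderm cells.

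The rank was divided into 10 bins of 668 or 669 cells, and the passage from ectoderm to mesoderm lay between bins 5 and 6. Because each rank was used once, the point of transition depends on how many cells of each tissue were captured. Ectoderm supplied 84.4% of the cells in bin 2 (95% interval 81.5 to 87.1%), 54.0% in bin 5 (50.2 to 57.9%) and 13.2% in bin 6 (10.70 to 15.98%). Mesoderm supplied 25.1% in bin 5 (21.9 to 28.6%) and 60.5% in bin 6 (56.7 to 64.2%). The primitive streak supplied 0.299% of bin 4 (0.0363 to 1.08%), 9.28% of bin 5 and 24.6% of bin 6, and then between 15.6 and 19.6% of each higher bin. Bin 1, with the lowest ranks, was made mostly of neural ectoderm-1 (351 cells, 52.5%, interval 48.7 to 56.4%) and endoderm (233 cells, 34.9%, 31.3 to 38.6%). Bin 10 was made of mesoderm-4 (265 cells, 39.6%, 35.9 to 43.4%), mesoderm-2 (170 cells, 25.4%), the primitive streak (123 cells, 18.4%) and mesoderm-1 (81 cells, 12.1%), with few others. None of the 2481 ectoderm cells was in bin 10, which allows a share of up to 0.121%. None of the 783 mesoderm-1 cells and none of the 666 mesoderm-4 cells was in the lowest 4 bins, which allows up to 0.383% and 0.450%, respectively.

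**Figure D2:**
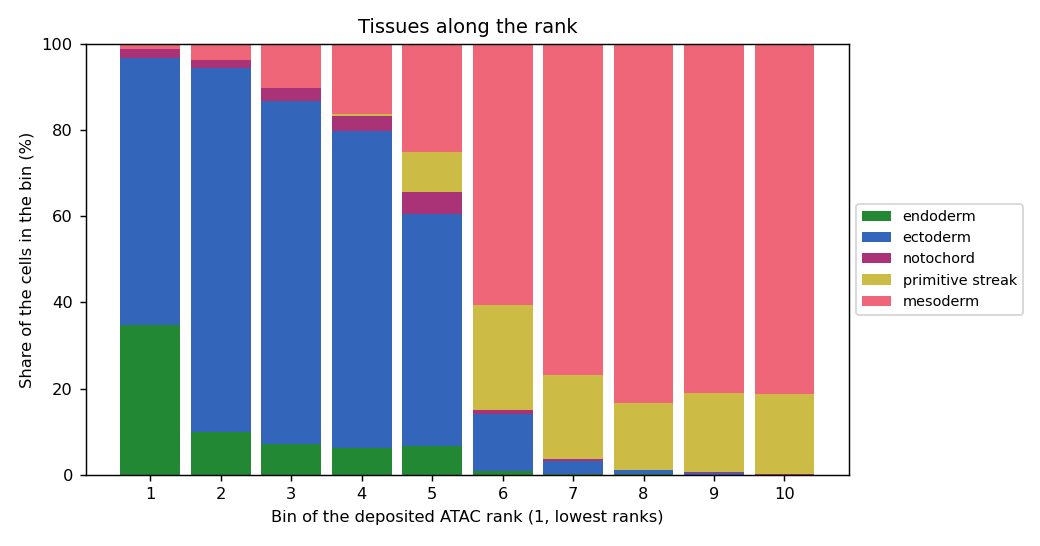
Share of cells of each tissue (vertical axis, percent of the 668 or 669 cells) in each of 10 bins of the deposited ATAC rank (horizontal axis, bin 1 holds the lowest ranks). Ectoderm makes up 54.0% of bin 5 and 13.2% of bin 6, where mesoderm makes up 60.5%.

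In the embedding, the primitive streak stood between ectoderm and mesoderm, and the rank was graded across it. Streak cells that bordered ectoderm (65 cells) had a median rank of 3458 (quartiles 3153 and 3962), and those that bordered mesoderm (117 cells) had a median of 5657 (quartiles 4734 and 6228). In neural ectoderm-2, the 41 cells bordering the streak had a median of 3182 (quartiles 2958 and 3367), against 2023 (quartiles 1437 and 2584.5) for the cells with no such border. In mesoderm-2, the 84 cells bordering the streak had a median of 6020 (quartiles 5569.5 and 6493.25), against 4685 (quartiles 3828 and 5667.5) for the others. In mesoderm-6, the 26 cells bordering the streak had a median of 5493.5 (quartiles 4146.5 and 5949), against 4605.5 (quartiles 4056.25 and 5184.5). In mesoderm-4, the 17 cells bordering the streak had a median of 5761 (quartiles 4849 and 6255), against 5799 (quartiles 5070 and 6280). The quartile ranges of these paired groups were disjoint in neural ectoderm-2 and overlapped in all 3 mesoderm classes named. At other borders, the 72 neural ectoderm-2 cells beside neural ectoderm-1 had a median of 1161.5 (quartiles 889 and 1591.5), and the 73 mesoderm-2 cells beside mesoderm-5 had a median of 3590 (quartiles 3215 and 4306). The 38 mesoderm-4 cells bordering blood islands had a median of 5126.5, against 5858 for cells with no such border, and their quartile ranges overlapped.

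**Figure D3:**
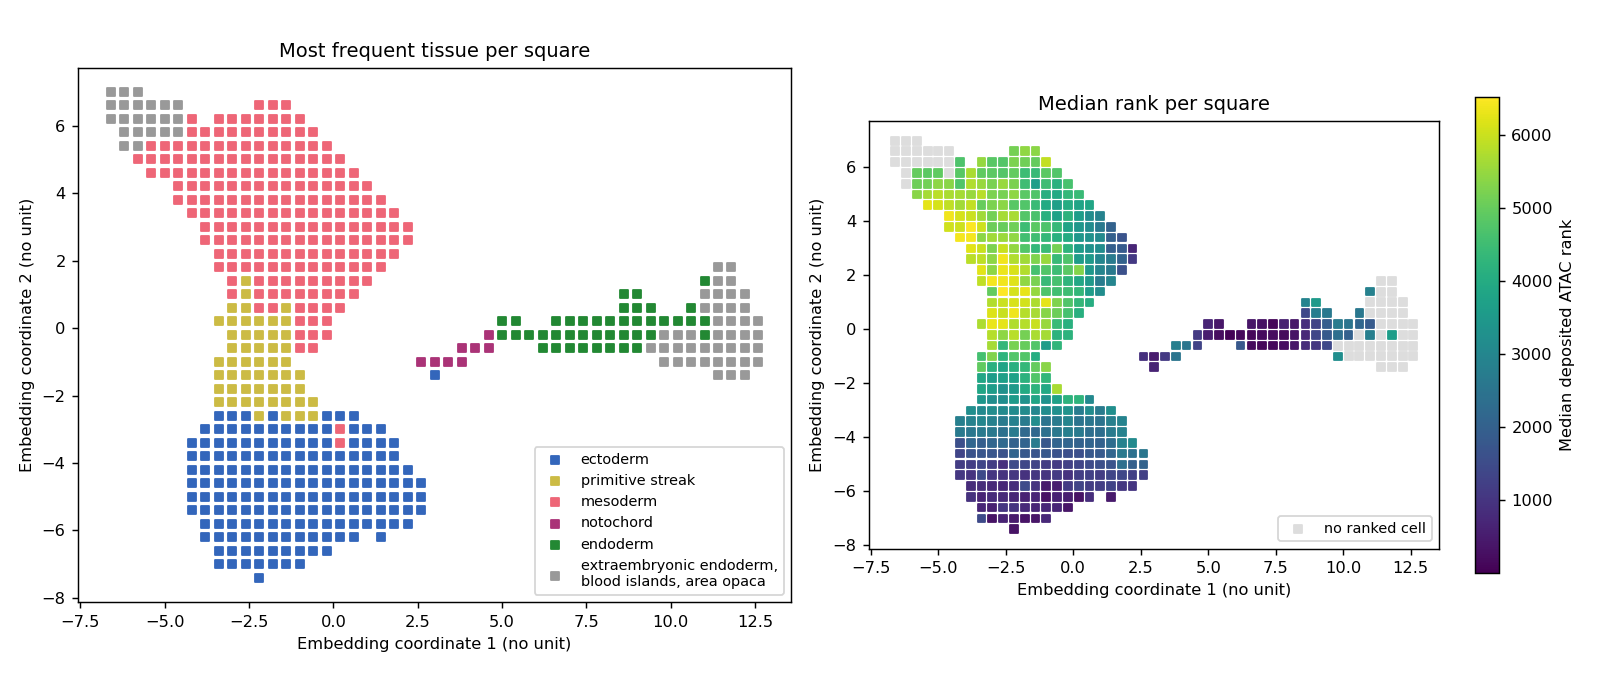
Map of the embedding of 7750 cells, with both axes in embedding coordinates (no unit) and each square 0.4 wide; the left panel is coloured by the most frequent tissue in a square and the right panel by the median deposited ATAC rank of its cells. Low ranks lie at the far end of ectoderm and in endoderm, and the primitive streak joins ectoderm to mesoderm with a median of 3458 beside ectoderm and 5657 beside mesoderm.

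Endoderm and notochord formed a separate arm that led to the extraembryonic endoderm and area opaca. The 37 endoderm cells bordering extraembryonic endoderm had a median rank of 1993 (quartiles 1747 and 2308), and the 403 others had a median of 462 (quartiles 141 and 1454). The border cells were not shown to hold the highest endoderm ranks. The 100 endoderm cells with a first embedding coordinate of 9 or more had a median of 2317 (quartiles 1804.25 and 2752.25), and the 340 below it a median of 329. These 100 cells can include border cells, and the quartile ranges of the 100 cells and the 37 border cells overlapped. Their medians therefore do not show where the highest ranks lay. The rank of an endoderm cell correlated with the first embedding coordinate, which runs along this arm, with Spearman's rho = 0.68 across 440 cells. Endoderm had the lowest median of the 13 ranked classes, but by means neural ectoderm-1 lay lower (875 against 1026).

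Cells near each other in the embedding had similar ranks, and the degree differed between classes. Over all ranked cells, Spearman's rho between the rank of a cell and the median rank of its 15 nearest cells was 0.93. Within classes, with the nearest cells taken from the same class, the mean rho weighted by cells was 0.61. The rho of a class was highest in mesoderm-5 (0.82), the primitive streak (0.78), nonneural ectoderm-1 (0.78), neural ectoderm-2 (0.78) and endoderm (0.77). It was lowest in mesoderm-4 (0.32), mesoderm-1 (0.35) and neural ectoderm-1 (0.37). A rho within a class can also depend on how widely its ranks spread, which was not adjusted for. The standard deviation (SD) of the rank was 629 to 812 in these lowest classes and 821 to 1095 in the highest ones. Nonneural ectoderm-2 (SD 795, rho 0.76) and the notochord (SD 1196, rho 0.60) went the other way. These values are across cells, which are not independent replicates, and the embedding itself was partly built from the ATAC profiles.

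Most classes were compact in the embedding. By its header the class column holds cluster names, so the classes may rest on the same profiles as the embedding. Compactness may then be built in and is not an independent result. On average 89.6% of the 15 nearest cells carried the class name of the cell itself, where random mixing of the classes would give 7.72%. This share was 97.0% in endoderm, 96.9% in extraembryonic endoderm and 96.6% in blood islands, and 94.5% in the notochord. Mesoderm-2 was less compact at 79.99%. Mesoderm-3 stood apart at 26.6%, and mesoderm-2 supplied 45.7% of its nearest cells. Its median rank was 3857 (quartiles 3059 and 4359.25), and it was 4477 over the 29 cells that remained when those with fewer than 8 of 15 nearest cells in their own class were left out.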

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

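Of the 16 shares of cells, 15 stayed within their counting intervals when cells with fewer than 8 of their 15 nearest cells in their own class were left out, a choice made after seeing the data. The exception was mesoderm-3, whose share became 0.406% and whose median rank became 4477, because 107 of its 136 cells were removed; the median ranks of the other 12 classes stayed within their binomial intervals. With means in place of medians, 10 of 13 classes stayed within these intervals, and the mean was 1026 in endoderm, 875 in neural ectoderm-1 and 5617 in mesoderm-4. By means, neural ectoderm-1 came below endoderm. Within classes, Spearman's rho of the rank was -0.11 with the first embedding coordinate (-0.43 over all cells), 0.28 with the second (0.72) and 0.61 with the median rank of the nearest cells (0.93). The means for the coordinates average classes of opposite sign, such as 0.68 in endoderm and -0.82 in mesoderm-5 for the first, and 0.78 in neural ectoderm-2 and -0.56 in mesoderm-2 for the second, so they do not show how much of those relations lay between classes. The share of rank variance between classes, 77.2% as reported, was 76.3% without endoderm and 70.0% on normal scores of the ranks. Over all ranked cells, Pearson correlations moved each of the 3 relations by less than 0.1, and so did 5 or 50 nearest cells for the nearest-cell relation. Within single classes, some moved further. The Pearson value was 0.56 in endoderm for the first coordinate and 0.67 in neural ectoderm-2 for the second. Other numbers of nearest cells were not tried within classes for this relation. No paired analysis was possible because the 2 libraries are the RNA and ATAC parts of the same cells and no groups of samples were compared. Settings that drop cells by RNA molecules or ATAC fragments, and the correlations adjusted for depth, were planned but not run, because depth per cell was not analysed here. Whether depth differs along the rank is therefore not known.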

Other observations

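All tests in this part were chosen after the class medians had been seen, except the correlation of the rank with the order of the table and the test for doublets. Nonneural ectoderm-1 was divided at a first embedding coordinate of 0, a cut set by hand. Whether a gap separates the parts was not measured. The smaller part, below 0, held 137 of its cells (33.2%) and lay beside neural ectoderm-2, which supplied 16.7% of its nearest cells. The larger part held 276 cells and lay beside nonneural ectoderm-2. The median rank was 3041 in the smaller part (quartiles 2621 and 3307) and 1784 in the larger (quartiles 1142.75 and 2472). Across the whole class, Spearman's rho of the rank was -0.46 with the first coordinate and 0.78 with the second. Both values span the smaller and the larger part, so they cannot tell a gradient from a step between them. One class name thus covered cells with different neighbours and ranks.

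The ordering of the classes along the rank invites a reading as position, but the classes also differ in cell identity. A rank that separated only germ layers is argued against by the mesoderm classes, which together accounted for 44.9% of the rank variance among mesoderm cells. Mesoderm-4 cells ranked above mesoderm-5 cells in 99.3% of pairs and their quartile ranges were disjoint. That pair has the highest and lowest mesoderm medians and was picked after these were seen, so it restates them. An order carried over from the rows of the table is argued against by a Spearman's rho of 0.0061 between rank and row number. A candidate reading is that low ranks are anterior, since the notochord extends forward from the anterior end of the streak and streak cells ranked above notochord cells in 94.9% of pairs. That order was seen before the reading was framed, and no test here separated position from cell identity, so the reading stays open. Sequencing depth per cell was not analysed here.

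Mesoderm-3 was scattered through mesoderm, with 22 of its 136 cells among ectoderm. Small class size is argued against by the notochord, a smaller class with 94.5% of nearest cells in its own class. The 113 mesoderm-3 cells among mesoderm ranked below the surrounding cells of other classes by a median of 1128 (median difference -1128, quartiles -1724 and -372). Of these 113 cells, 16 ranked above their surroundings. Mesoderm-2 cells differed from their surroundings by a median of -24, and 389 of 799 lay above. Those surroundings included other mesoderm-2 cells, so a small difference was built in and gives no like-for-like baseline for mesoderm-3. Doublets of an ectoderm and a mesoderm cell may lower the ranks of mesoderm-3 cells among mesoderm. Such doublets among ectoderm would be expected above their surroundings. The bounds were written before the result of this test but after the table had been seen, since the test uses nearest cells. They were a median difference over 500 for doublets and 0 or lower against them. The 22 cells among ectoderm differed by a median of -390.5 (quartiles -740.25 and 22.25), with 6 of 22 above. This median met the bound against doublets. The quartiles give the spread over these few cells and not the error of their median. With 6 of 22 cells above their surroundings and no doublet caller run, doublets are not excluded. The rank of a mesoderm-3 cell correlated with that of its surroundings with rho = 0.42, between the bounds set for following them or not, and a cell state shared across tissues was not tested.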
